A study of Mus musculus with 10 samples.

How the data were processed

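RNA of mouse dendritic cells was measured in 10 libraries, 5 labelled Ptbp1-deficient and 5 labelled wild type (WT), from mice aged 8 to 10 weeks. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was made into libraries, and these were sequenced on an Illumina HiSeq as paired 150 bp reads. HISAT2, StringTie and DESeq2 were used by the authors, per the submitters' processing notes, which give no versions. Those notes name the human build GRCh38, whereas the deposited gene identifiers are mouse Ensembl identifiers. The counting tool and the use of strand are not given in the sources used here, so whether reads of antisense genes were told apart is not known. Reads called ambiguous, 1.78% to 1.94% of each library's counts, were kept out of the gene rows.

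The deposited count table holds unnormalized counts per gene and library, with rows for reads outside genes, ambiguous, of low quality, not aligned and not unique. Its 19178 gene rows have at least 2 counts in every library, so genes with fewer counts in any library are absent. The rows for genes hold 69.4% to 74.1% of each library's counts, reads outside genes 17.2% to 22.2%, and reads that were not unique 4.51% to 5.08%, the last being kept out of the gene rows. The tool behind the deposited FPKM table is not given in the sources used here. It has 11978 rows with a minimum of 1.00 in every library, and 10 repeated identifiers were summed. Of its identifiers 11723 are in the count table. Symbols, biotypes and coordinates came from the GENCODE M21 annotation of GRCm38, which matched 19035 of the count table's identifiers (99.3%) and left 143 without a symbol.

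Genes were filtered with edgeR's filterByExpr, which removed 930 and left 18248. TMM normalization and edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) compared Ptbp1-deficient with WT libraries, with genotype as the only term, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. No sex, batch or pairing term was used, and the labels do not say that each library came from a separate mouse. Of 37 gene lists fixed before the data were examined, 36 had enough measured members for camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Scores are the mean log2 CPM of a list's members with a prior count of 2. Single values were compared with exact two-sided permutation tests over all 252 assignments of 5 of 10 libraries.

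The named genes followed a rule fixed before the data were examined. It takes Ptbp1, Ptbp2 and Ptbp3, and the 10 rises and 10 falls largest in log2 fold change among changed genes with at least 5 CPM in the higher group, no overlap between groups and a symbol that is not a clone or pseudogene name. It also takes up to 4 changed members of each list with the smallest adjusted p, or the member with the highest CPM where none changed. Of the genes this gave, 4 are not reported here, and the other 140 entered the screen for single outlying libraries and the alternatives. The text gives full values for fewer, and which members of a list it prints was chosen after their values were seen, as were Bst2, Batf3, Rbpj, Klrd1 and Tm7sf2, named where a count was 5 or fewer.

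The alternatives planned before the data were examined were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom with quality weights, no filter, a floor of 1 CPM in 5 libraries, the replicate number as a block, and 1 surrogate variable from sva 3.50.0. The others were limma on log2 FPKM with pseudocounts of 1 and 0.1 and with a floor of 1, an adjusted p under 0.01, and leaving out each library in turn. Added after seeing the data were fits without Ptbp1-deficient replicates 1 and 2, without WT replicates 1 and 5, with the macrophage score as a covariate, and with the share of counts outside genes as a covariate. The fit was tested on simulated data drawn for the 18248 genes of this comparison: edgeR called 15 of 50 genes changed 1.25-fold, 32 of 50 changed 1.5-fold, 44 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 8 false calls. Only these genes, each with a mean of at least 1 CPM, were changed in the simulation. In the data 45.0% of the genes tested changed, so the simulated rates may not hold there.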

Results

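Poly(A) RNA of mouse dendritic cells, the antigen-presenting cells that prime T cells, was sequenced as paired 150 bp reads in 10 libraries. Of these, 5 came from Ptbp1-deficient mice and 5 from wild-type (WT) mice, all aged 8 to 10 weeks. Ptbp1 encodes polypyrimidine tract-binding protein 1, an RNA-binding protein that regulates splicing and mRNA fate, and the comparison asks which transcripts differ in dendritic cells that are deficient in it. Counts assigned to genes totalled 61759378 to 92697815 per Ptbp1-deficient library and 50516163 to 66153758 per WT library, and the deficient libraries were deeper on average (exact permutation test, two-sided, n = 5 and 5, p = 0.0397). The labels state neither the tissue of origin nor the sex of the mice, and they do not say that each library came from a separate mouse, so p-values measure only the spread between these libraries. Expression is given in TMM-normalized CPM with its SD over the 5 libraries of a group, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

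The level of Ptbp1 in every sample labelled deficient was below that of every WT sample, and its paralog Ptbp2 was higher. Ptbp1 (ENSMUSG00000006498, protein coding, chromosome 10, 79854427 to 79864771 on the plus strand of GRCm38) stood at 74.4 ± 1.08 CPM in the deficient group and 294 ± 21.1 CPM in WT, or 25.3% of the WT level (log2 fold change -1.98, SE 0.051, adjusted p = 1.9e-09). The highest deficient library had 75.7 CPM and the lowest WT library 259 CPM, and each library held at least 4562 Ptbp1 counts. Ptbp2, whose product is the paralog best known from neurons, stood at 135 ± 11.6 CPM against 73.9 ± 5.84 CPM, 182% of WT (log2 fold change 0.87, SE 0.070, adjusted p = 2.8e-06). Ptbp3 was at 420 ± 7.25 CPM and 399 ± 11.1 CPM (adjusted p = 0.12), and it passed with DESeq2 (log2 fold change 0.081, adjusted p = 0.042). In the deposited FPKM values the difference in Ptbp1 was smaller, 28.7 ± 6.02 against 65.3 ± 2.81 FPKM, a log2 fold change of -1.18 on the log2(FPKM + 1) scale with limma (adjusted p = 2.7e-05). The labels do not say which part of the gene was altered.

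**Figure D1:**
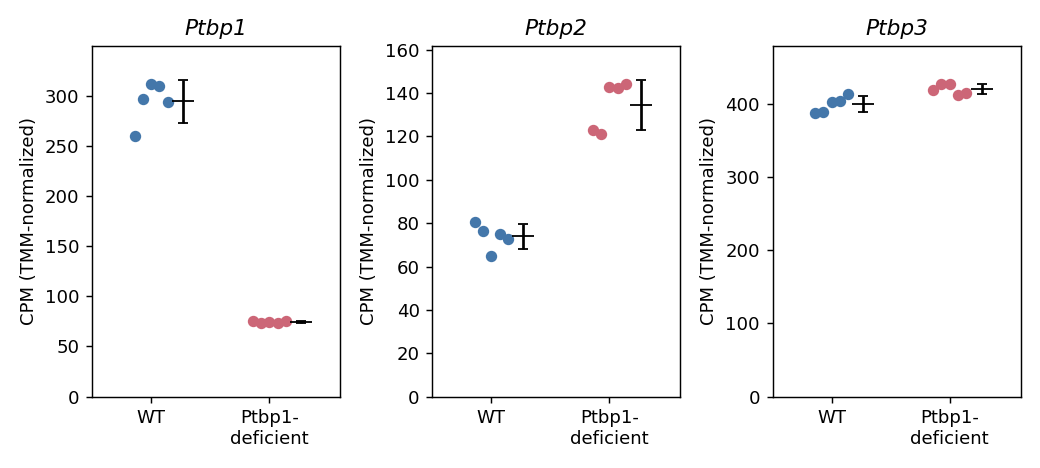
Expression of Ptbp1, Ptbp2 and Ptbp3 in each library, in TMM-normalized CPM on a linear axis from 0, with the group mean and SD (n = 5) beside the points. All 5 Ptbp1-deficient libraries lie between 73.2 and 75.7 CPM for Ptbp1, below the WT range of 259 to 312 CPM.

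The Ptbp1-deficient libraries had higher levels of interferon-stimulated, cell cycle, MHC class I, cDC1 and oxidative phosphorylation genes, and lower levels of cDC2 and NF-kB pathway genes, by camera with a preset correlation. With an estimated correlation camera called 0 lists, with 4 at an unadjusted p under 0.05, and fry called 16. Markers of macrophages and B cells were also lower, but WT replicates 1 and 5 stood apart in them, and without these libraries the B cell median log2 fold change went from -1.31 to -0.21, with 5 members higher and 8 lower. Of 17 NK cell markers 8 rose and 1 fell, with a median log2 fold change of 1.34. Without WT replicates 1 and 5, 15 NK cell markers rose and 1 fell. Among interferon-stimulated genes 42 of 43 rose, with a median of 2.40-fold, and all 40 measured cell cycle genes rose, with a median of 1.97-fold. Markers of cDC1, the dendritic cell type that cross-presents antigen to CD8 T cells, rose in 19 of 20 cases with a median of 1.95-fold. The steepest single rise was that of Abca13, which encodes a lipid transporter of the ABC family, from 4.23 ± 0.939 to 235 ± 50.6 CPM (55.7-fold, log2 fold change 5.80, SE 0.20, adjusted p = 1.7e-08).

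Of 18248 genes tested, 8214 changed, 3998 upward and 4216 downward. This balance varied, with 3456 upward and 4845 downward under upper-quartile normalization, and 2435 and 3261 in the FPKM values with a pseudocount of 1. By over 2-fold, 1103 genes fell and 610 rose. These counts were 870 and 816 without WT replicates 1 and 5, and 751 and 837 with the macrophage marker score as a covariate. That score itself separated the genotypes, so fits with it may also remove part of a genotype difference. The 5 libraries of one genotype did not overlap the 5 of the other for 6099 genes, 33.4% of those tested, where chance gives 0.794%. The first principal component held 47.6% of the variance and separated the genotypes (exact permutation test, two-sided, n = 5 and 5, p = 0.00794, the smallest p that this design can give). The second component held 17.9%, and WT replicate 5 stood farthest out on it. On the third (7.77%) deficient replicates 1 and 2 scored 29.3 and 27.8, and deficient replicates 3, 4 and 5 scored -19.1 to -18.7. The deficient libraries thus formed 2 clusters. WT libraries were not evenly spread either. WT replicates 2, 3 and 4 scored -36.85 to -34.47 on the first component and -32.28 to -23.08 on the second. WT replicates 1 and 5 scored -54.01 and -52.23 on the first and 3.93 and 62.94 on the second. The tests nevertheless treat all 5 libraries of each genotype as independent. The FPKM values, which list 11968 genes, gave fewer changes over 2-fold, 154 upward and 164 downward with a pseudocount of 1, and with a floor of 1 CPM in 5 libraries 648 genes fell by over 2-fold.

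**Figure D2:**
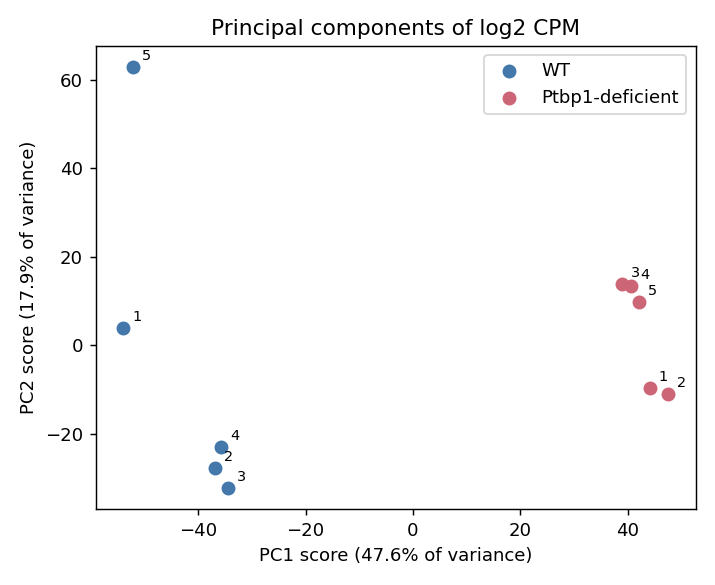
Scores of the 10 libraries on principal components 1 and 2 of log2 CPM over the tested genes, numbered by replicate within each group. Component 1 (47.6% of the variance) parts the genotypes, and WT replicate 5 lies apart from the other WT libraries on component 2 (17.9%).

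Besides Abca13, the 10 largest rises included 3 interferon-inducible GTPase genes and both Gzma and Gzmb. Iigp1, an immunity-related GTPase, rose from 4.16 ± 1.69 to 94.7 ± 27.96 CPM (22.8-fold, adjusted p = 7.6e-07). Tgtp1, another GTPase of that family, rose from 5.68 ± 0.660 to 81.4 ± 17.5 CPM (14.3-fold, adjusted p = 3.0e-08), and Gbp6, a guanylate-binding protein gene, from 0.741 ± 0.353 to 6.32 ± 1.15 CPM (8.50-fold, adjusted p = 9.4e-06). Ly6a, which encodes the surface antigen Sca-1, rose from 12.6 ± 8.10 to 164 ± 19.5 CPM (12.9-fold, adjusted p = 5.5e-06). Upp1, which encodes uridine phosphorylase, rose 17.7-fold, Apol7e 11.3-fold and Gpr33 7.12-fold, with adjusted p-values of 3.6e-07, 1.7e-05 and 2.2e-07. Upp1 and Abca13 lie near each other on the plus strand of chromosome 11 (9118103 to 9136170 and 9191942 to 9684259). Whether their rises are separate events was not tested. The granzyme genes Gzma (4.31 ± 7.22 to 53.1 ± 14.7 CPM, adjusted p = 0.0035) and Gzmb (0.918 ± 1.82 to 10.0 ± 1.72 CPM, adjusted p = 0.011) varied widely within WT, where replicate 5 alone reached 17.2 and 4.17 CPM. Tgtp1, Iigp1, Gbp6, Apol7e and Ly6a belong to families of close copies, so reads of their relatives may have been counted with them.

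The largest falls were in genes of differing functions. Cd207, which encodes langerin, stood at 2.27 ± 0.567 CPM against 37.7 ± 21.2 CPM in WT (log2 fold change -4.06, SE 0.42, adjusted p = 1.7e-05). Cd209d, a C-type lectin gene with close paralogs, stood at 0.792 ± 0.164 against 7.62 ± 2.19 CPM (log2 fold change -3.27, SE 0.22, adjusted p = 8.2e-07). Abca9, another ABC transporter gene, fell from 60.4 ± 6.68 to 6.82 ± 1.92 CPM (adjusted p = 3.1e-07) and Ppp1r9a, which encodes neurabin, from 16.3 ± 2.43 to 2.13 ± 0.292 CPM (adjusted p = 7.6e-08). Zfp532 fell by 3.41 and Mid2 by 3.14 on the log2 scale, with adjusted p-values of 7.5e-07 and 7.1e-06. Slpi, which encodes a secreted protease inhibitor, fell from 42.8 ± 28.6 to 3.44 ± 1.55 CPM (adjusted p = 6.8e-05). Col14a1 (24.9 ± 21.99 CPM in WT) and the macrophage scavenger receptor gene Cd163 (65.2 ± 69.3 CPM) also fell, with adjusted p-values of 0.0014 and 0.0027, and each was far higher in WT replicate 5 than in the other WT libraries.

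Interferon-stimulated genes rose nearly as a block, and no member of the list fell. Both over all genes tested and adjusted over the list alone, 42 of the 43 measured members rose; Bst2 was at 95.7 CPM against 76.9 CPM (adjusted p = 0.18). The GTPase gene Igtp rose from 23.6 ± 1.74 to 102 ± 12.6 CPM (4.30-fold, adjusted p = 3.9e-08) and Oasl2, of the oligoadenylate synthetase family, from 53.9 ± 5.17 to 239 ± 32.0 CPM (4.43-fold, adjusted p = 7.6e-08). The competitive camera test with a preset correlation of 0.01 gave the list an adjusted p of 1.6e-22 (median log2 fold change 1.26), against adjusted p = 0.25 with an estimated correlation. Without WT replicates 1 and 5, which carried the most macrophage transcripts, 43 members rose.

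Genes of MHC class I presentation, which loads peptides for CD8 T cells, rose with them. Of 23 members 21 rose and none fell, the same numbers adjusted over the list alone, with a median log2 fold change of 0.70. Tap1, the peptide transporter gene, rose from 442 ± 19.8 to 963 ± 57.4 CPM (2.18-fold, adjusted p = 1.2e-07). H2-T22 rose from 86.3 ± 3.01 to 200 ± 10.2 CPM (2.32-fold, adjusted p = 2.9e-08) and H2-Q4 from 355 ± 12.1 to 703 ± 48.1 CPM (1.98-fold, adjusted p = 2.5e-07). The H2-T and H2-Q genes are near copies of one another, which leaves their individual counts uncertain. Camera gave an adjusted p of 1.1e-13 with the preset correlation, against adjusted p = 0.27 with an estimated correlation. MHC class II presentation was not called by camera (adjusted p = 0.81): of 19 members 3 rose and 6 fell, the same numbers adjusted over the list alone. Among the latter, H2-Eb2 fell from 254 ± 28.8 to 166 ± 16.6 CPM (adjusted p = 1.5e-04) and the protease gene Ctsl, highest in WT replicate 5, from 22.8 ± 17.0 to 7.58 ± 2.31 CPM (adjusted p = 0.0078). Ctsl did not pass without deficient replicates 1 and 2 (adjusted p = 0.055) or with the macrophage marker score as a covariate (adjusted p = 0.70).

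Markers of the 2 conventional dendritic cell types moved in opposite directions. Of 20 cDC1 markers 19 rose, also adjusted over the list alone, and Batf3 was at 108 CPM against 100.78 CPM (adjusted p = 0.10). Xcr1, the chemokine receptor gene that defines cDC1, rose from 117 ± 16.3 to 376 ± 52.0 CPM (3.21-fold, adjusted p = 7.8e-07). The integrin gene Itgae rose from 46.6 ± 13.5 to 199 ± 35.3 CPM (4.28-fold, adjusted p = 7.0e-06) and Ly75, which encodes the endocytic receptor DEC-205, from 85.2 ± 5.02 to 155 ± 14.4 CPM (1.82-fold, adjusted p = 1.8e-06). Of 20 cDC2 markers 13 fell and Rbpj alone rose (14 and 2 adjusted over the list alone), with a median log2 fold change of -0.45. Besides Cd209d, the galactose-type lectin genes Clec10a (13.4 ± 2.69 to 3.61 ± 0.597 CPM, adjusted p = 3.6e-06) and Mgl2 (5.37 ± 1.72 to 1.04 ± 0.221 CPM, adjusted p = 1.3e-05) fell. Camera gave adjusted p-values of 2.8e-10 for cDC1 and 8.5e-04 for cDC2 with the preset correlation, against adjusted p = 0.53 with an estimated correlation for cDC1 and adjusted p = 0.25 with an estimated correlation for cDC2. Macrophage marker scores differed in the same libraries; without WT replicates 1 and 5, 18 cDC1 markers rose and 13 cDC2 markers fell.

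Transcription factors of dendritic cell development changed in both directions. Irf8, on which cDC1 depend, rose from 700 ± 88.1 to 1359 ± 229 CPM (1.94-fold, adjusted p = 6.1e-05), and Zeb2, a factor that opposes cDC1 development, fell from 133 ± 18.8 to 76.5 ± 4.66 CPM (log2 fold change -0.80, adjusted p = 2.3e-05). Over that whole list of 22 genes 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.96), and without deficient replicate 3, 4 fell. Of 18 plasmacytoid dendritic cell markers 3 rose and 7 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.46). Besides Cd209d, the transcription factor genes Tcf4 (95.8 ± 21.04 to 50.9 ± 4.62 CPM, adjusted p = 1.5e-04) and Spib (102 ± 34.4 to 46.2 ± 4.13 CPM, adjusted p = 2.8e-04) fell. The list's mean log2 CPM was 5.39 in WT replicate 5 and 3.78 to 4.33 in the other WT libraries. The RNase gene Rnase6 was at 287 ± 9.16 against 199 ± 12.7 CPM (adjusted p = 6.7e-06). The difference in Rnase6 did not pass in the FPKM values (log2 fold change 0.18, adjusted p = 0.060). Markers of mature migratory dendritic cells mostly fell, 16 of 24 against 3 that rose, the same numbers adjusted over the list alone, with a median log2 fold change of -0.37. Apol7c fell from 378 ± 27.8 to 240 ± 14.9 CPM (adjusted p = 6.7e-06) and Tmem123 from 676 ± 37.3 to 437 ± 32.5 CPM (adjusted p = 8.6e-06), while Serpinb6b rose from 74.9 ± 11.4 to 251 ± 38.1 CPM (3.36-fold, adjusted p = 1.2e-06). For this list camera gave an adjusted p of 0.0028, against adjusted p = 0.61 with an estimated correlation, and with the macrophage marker score as a covariate 9 members fell (camera adjusted p = 0.058).

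All 40 cell cycle genes rose, also adjusted over the list alone, with a median log2 fold change of 0.98. The mitotic kinase genes Plk1 (16.7 ± 1.64 to 41.02 ± 1.65 CPM, 2.46-fold, adjusted p = 2.0e-07) and Aurkb (26.3 ± 2.31 to 55.4 ± 1.75 CPM, 2.11-fold, adjusted p = 2.5e-07) rose, as did the centromere protein gene Cenpf (19.2 ± 1.36 to 41.6 ± 2.66 CPM, 2.16-fold, adjusted p = 2.7e-07). Camera gave an adjusted p of 2.4e-21, against adjusted p = 0.40 with an estimated correlation. All 40 genes also rose without WT replicates 1 and 5. Of 26 p53 targets and cell death genes 9 rose and 5 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.44). Among them were the pro-apoptotic gene Bak1 (107 ± 9.90 to 165 ± 9.60 CPM, adjusted p = 1.7e-05) and Ccng1 (81.3 ± 1.06 to 99.99 ± 1.87 CPM, adjusted p = 1.7e-05).

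**Figure D3:**
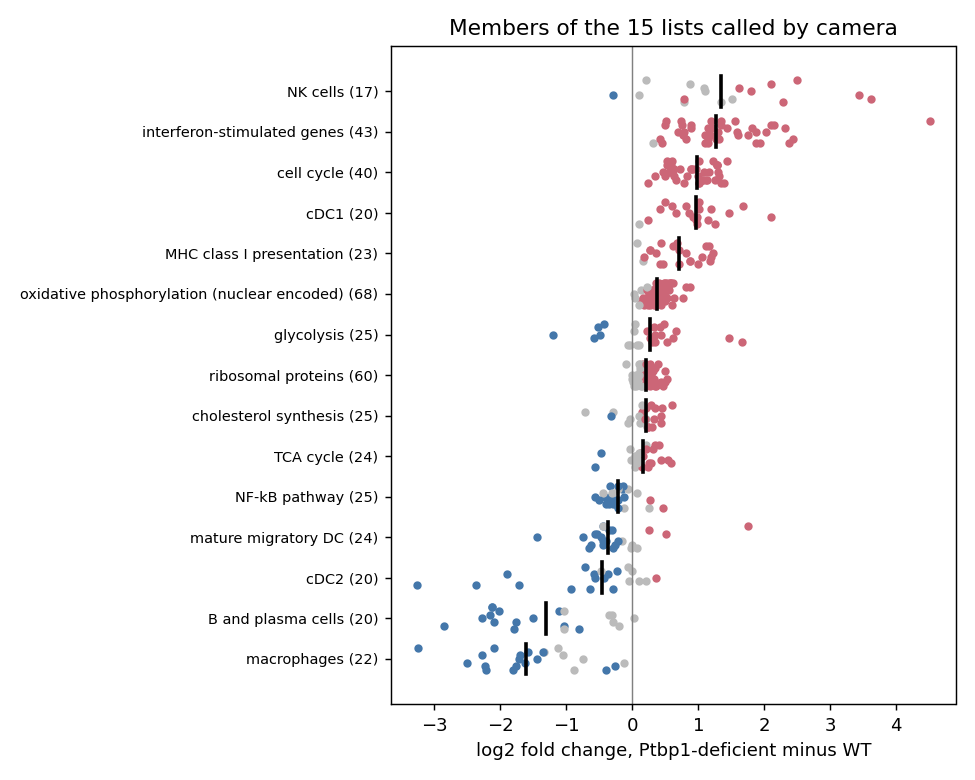
Log2 fold change (Ptbp1-deficient minus WT) of each measured member of the 15 gene lists called by camera with the preset correlation, with the number of measured members in brackets. Red points rose and blue points fell at an adjusted p below 0.05, grey points did not pass, and the black bar is the list median, from 1.34 for NK cell markers to -1.61 for macrophage markers.

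Most nuclear genes of mitochondrial respiration rose, each by less than 2-fold. Of 68 oxidative phosphorylation genes 63 rose and none fell (64 and 0 adjusted over the list alone), with a median log2 fold change of 0.37 and a range of 0.02 to 0.87. The complex I subunit genes Ndufa8 (46.4 ± 3.16 to 72.1 ± 1.53 CPM, adjusted p = 1.8e-06), Ndufa9 (49.98 ± 2.29 to 67.6 ± 3.18 CPM, adjusted p = 1.9e-05) and Ndufs6 (21.2 ± 1.29 to 31.4 ± 2.08 CPM, adjusted p = 2.0e-05) were examples. By camera the list had an adjusted p of 1.9e-17, against adjusted p = 0.53 with an estimated correlation. In the tricarboxylic acid cycle 13 of 24 genes rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.62 with an estimated correlation). Citrate synthase, Cs, was at 335 ± 10.6 against 231 ± 17.3 CPM (adjusted p = 1.2e-05), Suclg1 at 66.1 ± 4.01 against 43.9 ± 3.01 CPM (adjusted p = 9.8e-06) and Sdhd at 75.6 ± 5.14 against 57.3 ± 2.55 CPM (adjusted p = 8.8e-05). No transcript of the mitochondrial genome rose, and 5 of 15 fell, also adjusted over the list alone (camera adjusted p = 0.28). Among them were mt-Nd4 (860 ± 169 to 594 ± 43.8 CPM, adjusted p = 0.0030) and mt-Cytb (2292 ± 265 to 1753 ± 159 CPM, adjusted p = 0.0040), and without deficient replicate 1, 3 fell. Without deficient replicates 1 and 2, 2 fell, without WT replicates 1 and 5, 2 rose and 5 fell, and with the macrophage marker score as a covariate 1 rose and 1 fell. With the macrophage marker score as a covariate mt-Cytb did not pass (adjusted p = 0.064).

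Glycolysis genes changed in both directions, 14 upward and 5 downward of 25, the same numbers adjusted over the list alone. Pfkp, which encodes a phosphofructokinase, rose from 84.7 ± 4.47 to 234 ± 36.8 CPM (2.77-fold, adjusted p = 6.4e-07) and the hexokinase gene Hk3 from 65.3 ± 9.47 to 207 ± 38.7 CPM (3.16-fold, adjusted p = 2.5e-06). The enolase gene Eno2 fell from 20.6 ± 2.65 to 8.94 ± 1.47 CPM (adjusted p = 1.7e-05). The camera adjusted p was 0.031, against adjusted p = 0.62 with an estimated correlation, and it was 0.058 with the macrophage marker score and 0.075 with the share of counts outside genes as a covariate. Of 25 cholesterol synthesis genes 13 rose and Tm7sf2 fell (15 and 1 adjusted over the list alone). Hmgcs1 rose from 34.5 ± 3.36 to 46.8 ± 2.26 CPM (adjusted p = 2.5e-04) and Pmvk from 22.2 ± 1.89 to 30.2 ± 1.27 CPM (adjusted p = 1.4e-04). The camera adjusted p of that list was 0.0029, against adjusted p = 0.53 with an estimated correlation. Of 60 ribosomal protein genes 38 rose and none fell (40 and 0 adjusted over the list alone), with a median log2 fold change of 0.21. Rpl24, Rpl37 and Rpl3 rose by 0.50, 0.47 and 0.32 on the log2 scale (adjusted p = 1.5e-04, 1.8e-04 and 2.4e-04). For ribosomal proteins camera gave an adjusted p of 1.0e-07, against adjusted p = 0.81 with an estimated correlation, and 20 members rose with the macrophage marker score as a covariate.

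NF-kB pathway genes fell by small amounts, 16 of 25 against 2 that rose (17 and 2 adjusted over the list alone), with a median log2 fold change of -0.22. Nfkb2 fell by 0.42 on the log2 scale, SE 0.040 (adjusted p = 8.8e-06), the kinase gene Ikbkb from 276 ± 8.02 to 219 ± 6.19 CPM (adjusted p = 2.4e-05) and Traf3 from 168 ± 8.34 to 118 ± 10.2 CPM (adjusted p = 4.4e-05). Camera's adjusted p was 0.0018, against adjusted p = 0.53 with an estimated correlation. Lists of signalling molecules changed in both directions and were not called by camera. Of 23 cytokine genes 9 rose and 5 fell (9 and 6 adjusted over the list alone; adjusted p = 0.84). Il18 stood at 14.3 ± 2.10 against 31.9 ± 5.13 CPM (adjusted p = 2.1e-05) and Tnfsf10, which encodes the death ligand TRAIL, at 8.64 ± 0.583 against 5.21 ± 0.606 CPM (adjusted p = 9.3e-05). Of 26 chemokines and receptors 4 rose and 11 fell (4 and 12 adjusted over the list alone; adjusted p = 0.47), with Ccl9 at 5.86 ± 1.21 against 27.7 ± 2.17 CPM (adjusted p = 3.5e-07). Of 32 pattern recognition genes 12 rose and 9 fell (13 and 9 adjusted over the list alone, camera adjusted p = 0.40), and fry called the list higher (adjusted p = 1.8e-04). Ifih1, which encodes the RNA sensor MDA5, stood at 151 ± 9.44 against 85.3 ± 5.28 CPM (adjusted p = 7.8e-07) and the flagellin receptor gene Tlr5 at 12.9 ± 1.64 against 40.4 ± 5.38 CPM (adjusted p = 7.5e-07). Of 22 co-stimulatory and co-inhibitory genes 4 rose and 5 fell, the same numbers adjusted over the list alone (adjusted p = 0.96). Icosl stood at 326 ± 27.8 against 513 ± 34.7 CPM (adjusted p = 1.5e-05) and Tnfrsf14 at 71.7 ± 7.22 against 46.6 ± 1.82 CPM (adjusted p = 1.8e-05).

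Among the remaining lists of cell functions, camera called none. Splicing partners of PTBP1 and other hnRNP and SR factors rose in 10 and fell in 7 of 36 cases (11 and 8 adjusted over the list alone; adjusted p = 0.44). Hnrnph1 was at 609 ± 27.3 against 798 ± 13.5 CPM (adjusted p = 2.3e-05) and Hnrnpd at 295 ± 10.4 against 235 ± 7.10 CPM (adjusted p = 4.4e-05). The difference in Hnrnpd did not pass in the FPKM values (adjusted p = 0.15). Of 25 fatty acid metabolism genes 9 rose and 7 fell (9 and 8 adjusted over the list alone; adjusted p = 0.73), with the dehydrogenase gene Acadl at 114 ± 19.9 against 53.3 ± 10.7 CPM (adjusted p = 8.5e-05). Of 32 lysosome and phagocytosis genes 5 rose and 10 fell (5 and 12 adjusted over the list alone; adjusted p = 0.40), with the inhibitory Fc receptor gene Fcgr2b at 32.2 ± 4.03 against 78.2 ± 7.26 CPM (adjusted p = 1.2e-06). Of 22 unfolded protein response genes 5 rose and 6 fell (5 and 7 adjusted over the list alone; adjusted p = 0.84), with the stress kinase gene Eif2ak3 at 59.7 ± 5.56 against 94.0 ± 15.2 CPM (adjusted p = 3.9e-04). Dissociation and immediate-early stress genes fell in 13 of 27 cases, also adjusted over the list alone, and none rose (adjusted p = 0.0504). Egr1 fell from 2832 ± 571 to 1005 ± 75.7 CPM (adjusted p = 5.3e-06) and Jun from 2595 ± 869 to 1007 ± 106 CPM (adjusted p = 2.7e-04). The competitive test of dissociation and immediate-early stress genes gave an adjusted p of 5.2e-04 without WT replicate 1 and 0.037 without WT replicate 2. Over all libraries it was adjusted p = 0.98 with an estimated correlation. Without WT replicates 1 and 5, 8 members rose and 15 fell.

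Markers of other immune cell types differed between the genotypes and between libraries of 1 genotype. Of 22 macrophage markers 16 fell and none rose (18 and 0 adjusted over the list alone), with a median log2 fold change of -1.61. Lyz2, the lysozyme gene, fell from 388 ± 177 to 119 ± 20.6 CPM (adjusted p = 1.7e-04), Apoe from 493 ± 292 to 146 ± 43.8 CPM (adjusted p = 0.0011) and Cd68 from 206 ± 8.70 to 172 ± 13.2 CPM (adjusted p = 0.0024). The mean log2 CPM of the macrophage list was highest in WT replicates 5 and 1 (7.40 and 6.68), between 5.74 and 5.81 in the other WT libraries, between 5.27 and 5.53 in Ptbp1-deficient replicates 3, 4 and 5, and lowest in deficient replicates 1 and 2 (3.76 and 3.55). When WT replicates 1 and 5 were left out, 10 macrophage markers fell. Leaving out deficient replicates 1 and 2 gave 13 lower macrophage and 4 lower B cell markers. Of 20 B and plasma cell markers 13 fell and none rose, the same numbers adjusted over the list alone. The kinase gene Blk stood at 19.8 ± 2.32 against 40.5 ± 3.24 CPM (adjusted p = 2.7e-06), the complement receptor gene Cr2 at 5.38 ± 0.649 against 23.5 ± 15.2 CPM (adjusted p = 3.0e-04) and Fcer2a at 2.10 ± 0.686 against 15.2 ± 18.2 CPM (adjusted p = 0.0039). Without WT replicate 5 the camera adjusted p of the B cell list was 0.0999. The camera adjusted p-values were 1.4e-04 for macrophages and 0.020 for B cells, against adjusted p = 0.81 with an estimated correlation for macrophages and adjusted p = 0.98 with an estimated correlation for B cells. With the macrophage marker score as a covariate neither Cd68 (adjusted p = 0.093) nor Fcer2a (adjusted p = 0.42) passed.

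NK cell markers went the other way. Of 17 members 8 rose and Klrd1 fell, also adjusted over the list alone, with a median log2 fold change of 1.34. The receptor gene Klrk1 rose from 34.1 ± 3.15 to 105 ± 11.4 CPM (adjusted p = 1.8e-07), the transcription factor gene Tbx21 from 22.4 ± 4.17 to 38.5 ± 4.14 CPM (adjusted p = 2.7e-04) and Klre1 from 1.84 ± 1.06 to 6.40 ± 1.248 CPM (adjusted p = 4.8e-04). WT replicate 5 again stood apart, with a list score of 2.79 against at most 1.17 in the other WT libraries, and without it 14 members rose. The camera adjusted p was 4.3e-04, against adjusted p = 0.62 with an estimated correlation, and 2 members rose in the FPKM values. The other lists of cell types were not called by camera. Of 19 T cell markers Tcf7 alone fell (72.3 ± 6.85 to 31.6 ± 3.06 CPM, adjusted p = 7.6e-07; camera adjusted p = 0.47), and the competitive test of T cells called the list higher without WT replicate 5 (adjusted p = 9.1e-04). Over all libraries the T cell list had adjusted p = 0.98 with an estimated correlation, and 18 of its 19 members did not pass. Of 16 monocyte markers 2 rose and 7 fell (camera adjusted p = 0.40), with Ms4a4c at 225 ± 18.2 against 108 ± 8.72 CPM (adjusted p = 6.6e-07) and Ace at 31.2 ± 3.75 against 104 ± 17.6 CPM (adjusted p = 8.1e-07). Of 16 neutrophil markers Mmp9 (33.9 ± 10.5 to 11.3 ± 2.86 CPM, adjusted p = 3.4e-04) and Csf3r (46.7 ± 14.3 to 27.2 ± 6.45 CPM, adjusted p = 0.0087) fell (camera adjusted p = 0.84). Csf3r did not pass without deficient replicates 1 and 2 (adjusted p = 0.063) or with the macrophage marker score as a covariate (log2 fold change -0.15, adjusted p = 0.53). Of 12 erythroid and platelet markers Epor fell, from 3.72 ± 2.20 to 0.628 ± 0.327 CPM (adjusted p = 8.6e-04; camera adjusted p = 0.84). None of 5 basophil and mast cell markers passed (camera adjusted p = 0.63), the most abundant being Hdc at 8.96 and 6.99 CPM, which passed without WT replicate 5 (adjusted p = 0.0019). Of 5 stromal, endothelial and epithelial markers Kdr rose from 9.24 ± 2.497 to 33.8 ± 3.23 CPM (adjusted p = 2.7e-06) and Pecam1 fell from 137 ± 9.03 to 113 ± 8.43 CPM (adjusted p = 0.0022; camera adjusted p = 0.96). For these 6 lists of cell types the counts were the same adjusted over the list alone.

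Of 37 lists fixed before the data were examined, 36 were tested and camera called 15 with the preset correlation. With an estimated correlation camera called 0, with 4 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance, called 16. Among the lists not called by camera, median, mean and test differed in sign for PTB family, cytokine, T cell, pattern recognition, fatty acid, basophil and stromal genes, and fry's direction differed for dendritic cell development. Of these lists fry called the PTB family lower (adjusted p = 1.2e-06) and pattern recognition genes higher (adjusted p = 1.8e-04).

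The genotype groups were not balanced for the X-inactivation transcript Xist, which female cells make. Xist stood at 3.34 and 2.66 CPM in Ptbp1-deficient replicates 1 and 2, at 830, 1757 and 1007 CPM in deficient replicates 3, 4 and 5, at 1671 to 1821 CPM in WT replicates 1 to 4 and at 864 CPM in WT replicate 5. Xist did not pass the test between the groups (adjusted p = 0.47). No Y-linked gene of the list was in the count table, which holds only genes with at least 2 counts in every library. The table does hold 5 other genes annotated on chromosome Y. Without deficient replicates 1 and 2 the numbers of interferon-stimulated, cDC1 and cell cycle genes that rose were 42, 19 and 40.

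**Figure D4:**
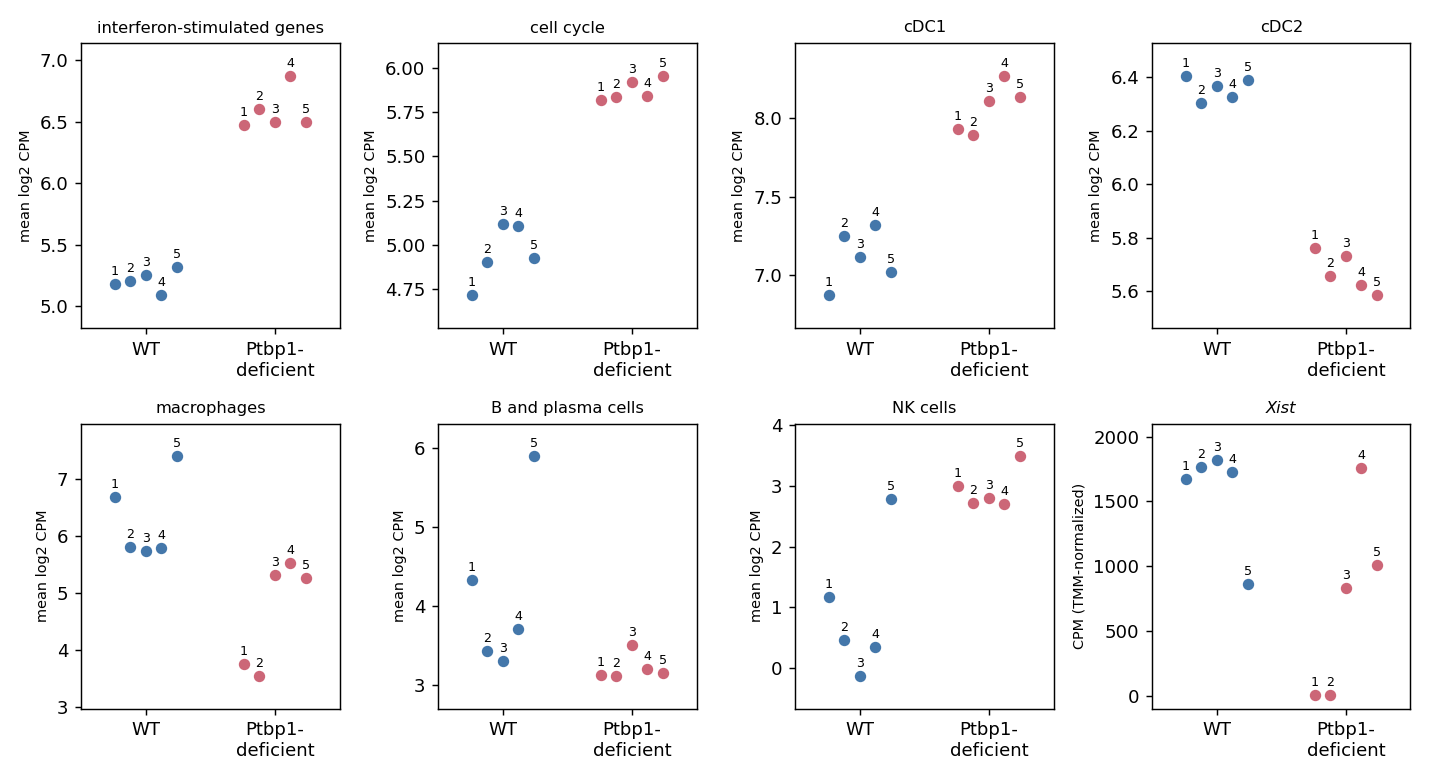
Mean log2 CPM over the members of 7 gene lists, and Xist in TMM-normalized CPM, for each library, numbered by replicate; the axes of the list panels do not start at 0. The interferon, cell cycle, cDC1, cDC2 and macrophage scores of the 2 genotypes do not overlap, whereas the B cell and NK cell scores do. Macrophage, B cell and NK cell scores also vary within genotypes, with WT replicate 5 the highest WT library in each.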

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

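Of the tests in this part, those without WT replicates 1 and 5, without deficient replicates 1 and 2 and of the correlations between markers were chosen only after the results were seen, although what the first would show was written before it was run.

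Lower macrophage and B cell markers coincided with libraries that stood apart, WT replicates 1 and 5 with the highest macrophage scores and deficient replicates 1 and 2 with the lowest (3.76 and 3.55). In the screen of 140 named genes for a library far from the other 4 of its group, 26 of 280 gene and group pairs stood out, where chance gives about 1 in 20, or 14, and 14 of the 26 were in WT replicate 5. Within genotypes, macrophage markers varied together across libraries with a mean pairwise correlation of 0.834, against an upper bound of 0.142 on the central 95% of random lists, so RNA of macrophages carried over in differing amounts may account for part of the pattern. Without WT replicates 1 and 5, 18 macrophage and B cell genes fell and 5 B cell genes rose, the macrophage median log2 fold change went from -1.61 to -0.89 and the B cell median from -1.31 to -0.21, which leaves open how much of the difference rests on those libraries. Without deficient replicates 1 and 2, 13 macrophage and 4 B cell genes fell (medians -1.16 and -1.22), and a change of these transcripts within the dendritic cells deficient in Ptbp1 was not tested separately and also stays open.

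WT replicate 5 was the highest WT library for Lyz2 (696 CPM), Apoe (1008 CPM), Cd163 (184 CPM), Cr2 (49.97 CPM), Fcer2a (46.96 CPM), Ctsl (52.03 CPM), Spib (162 CPM) and Col14a1 (63.8 CPM). It was also the highest for Ly6a (26.8 CPM), Gzma (17.2 CPM), Gzmb (4.17 CPM), Klre1 (3.71 CPM) and Kdr (13.6 CPM), and the lowest for Xist (864 CPM).

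In WT replicate 1 Serpinb6b (55.3 CPM) and Plac8 (249.5 CPM) lay below the other WT libraries. In WT replicate 2 Myd88 (86.1 CPM) and Atp6v1a (70.9 CPM) lay below them, and in WT replicate 3 Oasl2 (63.05 CPM) lay above them. Among deficient libraries, replicate 3 was lowest for H2-T22 (183 CPM) and highest for Cx3cr1 (21.1 CPM). Replicate 4 was highest for Zbp1 (258 CPM), Fscn1 (241 CPM) and Kdr (39.5 CPM), and replicate 5 for Apol7e (8.78 CPM) and Klre1 (8.62 CPM).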

How the results depend on the processing

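The fits without Ptbp1-deficient replicates 1 and 2, without WT replicates 1 and 5, with the macrophage score and with the share of counts outside genes were chosen only after the results were seen. Across the alternatives 5668 (adjusted p below 0.01) to 9147 (limma-voom) genes changed, 7239 to 8368 when 1 library was left out, and no named gene changed direction with a call. Of 140 named genes 137 passed and 125 passed under every alternative that lists them, other than the adjusted p below 0.01, which was applied to counts and lists and not to single genes. Of the 137, 12 failed at least once. By setting, 5 failed in the FPKM values and 8 with the macrophage score. The labels do not pair the replicate numbers, and same-numbered libraries deviated with correlations of -0.096 to 0.114. With the replicate block 7538 genes changed, 7341 of them shared, and 1 of 5 libraries correlated best with its own number. For the values below the cause was not tested, except that the FPKM table and the floor of 1 CPM hold fewer genes, and that the macrophage score is made of the macrophage list itself. That score was at most 5.53 in deficient and at least 5.74 in WT libraries. A fit with it therefore cannot cleanly separate genotype from macrophage transcripts.

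FPKM gave 2435 genes higher in each of its 3 forms. Genes over 2-fold higher numbered 154 with a pseudocount of 1, 220 with 0.1 and 154 with the floor, and genes over 2-fold lower 164, 251 and 164. With the floor of 1 CPM, 648 genes were over 2-fold lower. In all FPKM forms 5 B cell members were lower and 2 NK members higher.

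With the macrophage score as covariate, members lower were 9 for mature migratory DC, 2 for B and plasma cells and 7 for macrophages. Members higher were 3 for mature migratory DC, 6 for macrophages, 20 for ribosomal proteins and 14 for NK cells. The competitive test then gave 0.058 for mature migratory DC and glycolysis, 0.940 for B and plasma cells, 0.891 for macrophages, and a reversed 0.0045 for erythroid cells and platelets. With the share outside genes 3 B cell members were lower (test 0.108), and glycolysis gave 0.0750. Without WT replicates 1 and 5, 8 B cell members were lower and 5 higher, 10 macrophage members were lower, and 15 NK members were higher, the B cell test gave 0.461 and the competitive test of neutrophils a reversed 0.00958. Without Ptbp1-deficient replicates 1 and 2, 4 B cell members were lower (test 0.0666). Leaving out 1 library gave this test 0.0047 (without WT replicate 3) to 0.0999 (without WT replicate 5).

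At an adjusted p below 0.01, 25 ribosomal members were higher and 4 B cell members lower. Limma-voom gave 8 B cell members lower and 15 NK members higher, the replicate block 6 and 14, and 1 surrogate variable 14 NK members higher. Fry gave the B cell list 0.164 and the PTB family a reversed 1.2e-06.

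With an estimated correlation 0 lists were called by camera, against 4 at an unadjusted p under 0.05 and 16 called by fry. The adjusted p was 0.25 for interferon-stimulated genes and cDC2, 0.268 for MHC class I presentation, 0.405 for cell cycle, 0.533 for NF-kB pathway, cDC1, oxidative phosphorylation and cholesterol synthesis, 0.608 for mature migratory DC, 0.625 for glycolysis, TCA cycle and NK cells, 0.811 for macrophages, 0.813 for ribosomal proteins and 0.983 for B and plasma cells.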

Other observations

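Of the tests in this part, those without deficient replicates 1 and 2, without WT replicates 1 and 5, with the share of counts outside genes, of the cDC1 share, of the interferon type and of gene length and GC content, and all the gene families below, were chosen only after the results were seen. Proteasome subunit genes, whose products degrade proteins and make peptides for MHC class I, rose in 44 of 49 cases with none lower (median log2 fold change 0.40), with 1 lower in the FPKM values and without WT replicates 1 and 5. Mitochondrial ribosomal protein genes rose in 49 and fell in 3 of 76 cases (median 0.22), and in the FPKM values 30 rose and 5 fell (median 0.14). The Mcm genes, which include the replicative helicase, rose in 8 of 9 cases (median 0.63), with 1 lower under upper-quartile and voom, and chaperonin genes in 6 of 7 (median 0.31). Zinc finger genes with Zfp symbols fell in 169 and rose in 15 of 333 cases (median -0.25, negative under each normalization tried).

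Among genes of the interferon-gamma response, picked after their values were seen, edgeR gave Irf1 at 384 ± 29.7 against 195 ± 9.11 CPM (adjusted p = 3.5e-07) and the chemokine gene Cxcl9 at 191 ± 51.8 against 65.65 ± 11.65 CPM (adjusted p = 5.5e-05). Socs1 and Cxcl10 rose 2.15-fold and 2.61-fold (adjusted p = 2.0e-04 and 5.6e-05). Ifng itself was at 2.12 ± 0.649 against 0.438 ± 0.686 CPM (adjusted p = 0.024), with groups that overlapped. NK cell markers rose as well (8 of 17, with 1 lower), and which cells the Ifng transcripts came from was not tested. Ciita (1329 and 1274 CPM, adjusted p = 0.55) and Cd274 (238 and 227 CPM, adjusted p = 0.52) did not pass.

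The number of changed genes was compared with other splits of the libraries. Of the 126 splits into 5 and 5, 100 were drawn. The real split gave 8214 changed genes, and the highest other gave 1. Every other split mixes libraries of the genotypes, which widens the spread within its groups and leaves few calls whatever the cause. The real split thus stood out from those drawn. Any difference in batch, sex or handling that goes with genotype would give the same result, so none of these is excluded.

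The rise of interferon-stimulated genes was weighed against a higher share of cDC1 cells and against other cells in WT libraries. Within genotypes the interferon score followed the cDC1 score with a slope of 0.138 (SE 0.292), below the 1.45 that would be needed. In WT, however, the lowest cDC1 scores (6.87 and 7.02) were those of replicates 1 and 5, which had the highest macrophage scores (6.68 and 7.40). Other cells in differing amounts may thus have shaped the slope. It cannot decide on the cDC1 share, and no conclusion is drawn from it. Without WT replicates 1 and 5, 43 of 43 members rose, which argues against other cells in those 2 libraries. Their interferon scores (5.18 and 5.32) lay near the 5.09 to 5.25 of the other WT libraries, so leaving them out could change little. Whether other cells in the deficient libraries account for the rise was not tested. In the deficient libraries 8 NK cell markers were higher and 1 lower, and without WT replicates 1 and 5 these numbers were 15 and 1. Within genotypes NK cell markers varied together (mean pairwise correlation 0.537, upper bound of random lists 0.083), a measure chosen after the results were seen. RNA of NK cells in differing amounts may thus have been present. Guanylate-binding and immunity-related GTPase genes had a median log2 fold change of 1.64 and OAS, IFIT, MX and RSAD2 genes 1.29. An exact permutation test over genes compared their mean log2 fold changes (two-sided, p = 0.151). It treats genes that vary together as independent, and the type of interferon stays open. Without deficient replicates 1 and 2, which had almost no Xist counts, 42 members rose with a median log2 fold change of 1.32. This argues against a difference in sex of those libraries alone as the whole cause. Xist was still not balanced, at 830, 1757 and 1007 CPM in the deficient libraries left. It was at 864 CPM in WT replicate 5 and at least 1671 CPM in the other WT libraries. A difference in sex among the libraries left is therefore not excluded.

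The rise of oxidative phosphorylation genes was weighed against gene length and GC content and against RNA from outside genes. The list's median of 0.37 lay above 100% of 10000 random lists matched on length, GC content and expression, whose own median was 0.18. Length and GC content are thus unlikely to be the whole cause, but may account for part of the rise. With the share of counts outside genes as a covariate 63 members rose. That share averaged 18.0% in deficient and 19.3% in WT libraries (exact permutation test, two-sided, p = 0.222). The covariate could therefore remove little, and no conclusion is drawn from it. The median of ribosomal protein genes, 0.21, lay above 64.6% of matched lists, so length and GC content may account for it. Among the 13062 protein-coding genes tested, shorter genes were higher, with a median log2 fold change of 0.06 in the shortest and -0.10 in the longest of 5 groups of nearly equal size.

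The same matching was applied to proteasome genes, whose median lay above 100% of matched lists, and to zinc finger genes, whose median lay above 0% of them. Within 5 Mb of Ptbp1, 7.63% of 236 genes changed over 2-fold, against a median of 9.32% and a 95th percentile of 13.6% in random windows, which argues against a segment of another strain with many changed genes there.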
